A study of Mus musculus with 34 samples.

How the data were processed

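RNA of sorted CD4 T cells was made into 3-prime libraries (Lexogen QuantSeq, which reads the 3-prime end of each transcript, so a gene's count does not scale with its length). The authors deposited one table of raw counts per library, with numeric gene identifiers, and the deposited values were whole counts in every table. The submitters' processing notes name STAR 2.7.2b, featureCounts 1.6.4 and mm10 without roles, and give neither the strand setting nor the handling of reads that fit several places, so counts of overlapping or antisense genes and of close paralogs carry that uncertainty. Of 27179 identifiers 25275 were matched to a symbol and a position in the GRCm38.p6 annotation by identifier, and 1904 had none. Those 1904 held 48.8% of all counts, and identifiers 100861531 and 19791 alone held 48.3% of all counts. A table that joins all libraries repeats the same values and was not used here. No library labelled Tfh2_2e4 replicate 3 or TfhA_4e4 replicate 4 was among the 34 libraries.

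Total counts were 4481509 to 9934245 per library, and 12247 to 13276 genes had a count. A count of 0 is read as up to 3 counts over the group, and the lower bounds on folds use that floor. Counting intervals are at 95%, and intervals and floors cover counting error only, since the libraries carry no molecular identifiers. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure the spread between these samples. Of 80 pairs of libraries with the same replicate number, 15 correlated above 0.1 after removal of the group means. The mean correlation was 0.0494 for the same number, 0.0288 for other numbers of the same range (1 to 3 or 4 to 6) and -0.0354 across the ranges, and 15 of 34 libraries correlated best with their own number. The labels do not say what the numbers pair, so samples were not paired, and a replicate block was fitted as an alternative.

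Counts of all 34 libraries in 6 groups were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM normalization, the filter filterByExpr by group (11357 genes tested) and two-sided quasi-likelihood F-tests, adjusted by Benjamini and Hochberg over all genes with a threshold of 0.05. The comparisons were the 3 pairs of codes at 4e4, the slope of the group means on log2 of the label number within Tfh2, 6e4 against 1e4, and the 3 steps between neighbouring numbers. CPM values are counts scaled to a common normalized library total, with the SD over libraries, and log2 CPM per library used a prior count of 1. That total includes the counts of identifiers 100861531 and 19791. Unless the text says otherwise, fold changes are on the log2 scale, and values in brackets after a gene are its log2 fold change followed by its edgeR adjusted p.

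Lists of genes were tested with camera (limma 3.58.1) with a preset correlation of 0.01, again with the correlation estimated per list, and with fry, whose p tests whether a list's genes move, on balance, one way and does not compare them with other genes. Adjustment was over the lists of a comparison. Where only the camera p of a list that passed in the main fit is given, the list also passed with the estimated correlation. Its adjusted p was then larger, often by many orders of magnitude. Of 39 lists, 28 had at least 5 measured members and a test. One list, the mitochondrial mRNAs, was added after the data were seen. The comparisons, tests, lists, named genes' rule and most alternatives were chosen before the data were examined. The named genes are the 16 lineage genes, the 6 largest rises and 6 largest falls, and up to 4 members per list that passed with a mean log2 CPM of at least 1. Rises and falls needed a mean log2 CPM of at least 3, and predicted genes were passed over. Each library of the first group of a comparison (for steps, the higher number) had to lie on the same side of the other group's mean. Libraries of that other group were not checked singly, and counts of libraries higher or lower are of the same kind. For the slope, every step of the group means had to go the same way. Not every gene that this rule gives is named in the text.

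The design was tested on simulated data. Only a small part of the genes was changed, about equally up and down. Counts were drawn independently per gene from the kind of model that edgeR fits. Most of the real comparisons called far more genes, so the rates below need not hold for them. With a simulated change of 1 on the log2 scale between the groups, edgeR called 60.6% of the changed genes for TfhA_4e4 against Tfh2_4e4. It called 63.6% for Tfh5_4e4 against Tfh2_4e4. For the slope the simulated change was 1 per doubling of the label number, and 93.9% were called. That change is larger over the whole range of numbers, so the slope percentage cannot be compared with the others at an equal change. No call had the wrong sign. False calls made up 8% of the calls (9 of 113) for TfhA_4e4 against Tfh2_4e4, 6.1% (7 of 115) for Tfh2_2e4 against Tfh2_1e4 and 0% to 4.8% for the other comparisons. Identity of libraries was checked over the 80 pairs within groups, of which 0 were identical. Alternatives were relative log expression size factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, both ranges of replicate numbers as a factor, and each library left out in turn. Alternatives added after the data were seen are named in the closing section. One of the tested lineage genes is not reported here.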

Results

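RNA was counted in 34 libraries from naive CD4 T cells of C57BL/6 mice. The cells had been stimulated for several days on plates coated with antibodies to CD3 and CD28 and then sorted by flow cytometry. Each label carries a culture code and a number. Code Tfh2 was present with the numbers 1e4 (6 libraries), 2e4 (5), 4e4 (6) and 6e4 (6), and codes Tfh5 (6 libraries) and TfhA (5) with the number 4e4. The labels state neither what the codes stand for, nor the unit of the number, nor the gate of the sort, so groups are named by their labels. The series title names TGF-beta, the choice between the follicular helper (TFH) and TH17 fates, and the transcription factor c-Maf. The labels do not tie the 3 codes at 4e4 or the 4 numbers within Tfh2 to any of these.

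Total counts ranged from 4481509 to 9934245 per library. The group ranges were 8272173 to 9245808 in Tfh2_1e4, 5453857 to 9003008 in Tfh2_2e4, 6548499 to 9934245 in Tfh2_4e4 and 6610836 to 9247251 in Tfh2_6e4. They were 6181166 to 9543117 in Tfh5_4e4 and 4481509 to 8207111 in TfhA_4e4. Identifiers 100861531 and 19791, which have no symbol in the annotation used, held on average 31.4% and 17.0% of all counts. The rest came to between 2292557 and 5343465 counts per library. The mitochondrial rRNA genes took 14.8% ± 2.19 (n = 5) of that rest in TfhA_4e4 against 9.92% ± 0.989 (n = 6) in Tfh2_4e4 and 9.81% ± 1.24 (n = 6) in Tfh5_4e4. Of the 16 lineage genes fixed for the comparisons, 11 passed the filter on low counts. Il4 (a TH2 cytokine) had 0 counts in every group, which allows up to 0.0575 to 0.104 CPM (counts scaled to a common library total) by group. Foxp3, the regulatory T cell factor, had 62 counts summed over Tfh2_1e4, 10 over Tfh2_4e4, 23 over Tfh5_4e4 and 0 over TfhA_4e4. Bcl6, the transcriptional repressor that drives the TFH fate, had between 6 counts (TfhA_4e4) and 38 counts (Tfh5_4e4) per group. Prdm1, its antagonist, had between 8 and 38 and Ifng, the TH1 cytokine, between 0 and 9. These genes did not pass the filter. In the edgeR fit without it Foxp3 fell by 1.54 per doubling of the number within Tfh2 (SE 0.504, adjusted p = 0.00295). Foxp3 also passed as lower in Tfh2_6e4 than in Tfh2_1e4 (edgeR adjusted p = 0.00192) and lower in TfhA_4e4 than in Tfh5_4e4 (0.0107), but not against Tfh2_4e4 (0.0669). Ifng passed as falling per doubling (edgeR adjusted p = 0.0385) on 15 counts in 3 libraries, and Bcl6 and Prdm1 passed in none of the 8 comparisons.

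TfhA_4e4 cells differed from Tfh2_4e4 cells in most lineage genes measured. Maf, which encodes c-Maf (identifier 17132, GRCm38.p6 chromosome 8, 115703253 to 115706894), went from 629.6 ± 114.7 CPM (SD, n = 6) in Tfh2_4e4 to 18.8 ± 2.72 CPM (n = 5) in TfhA_4e4. It fell by 5.06 on the log2 scale (SE 0.135, edgeR adjusted p = 6.93e-31, lower in 5 of 5 libraries). The TH17 cytokine genes Il17a and Il17f, which lie side by side on chromosome 1 (20730905 to 20734496 and 20777146 to 20785274), had log2 fold changes of -6.68 and -6.11. Their levels went from 73.7 ± 33.6 to 0.692 ± 0.316 CPM and from 117 ± 18.8 to 1.66 ± 0.659 CPM. Cxcr5, the receptor that guides T cells into B cell follicles (chromosome 9, 44511787 to 44526444), fell by 3.58, from 8.26 ± 1.27 to 0.689 ± 0.772 CPM. Tbx21, which encodes the TH1 factor T-bet (chromosome 11, 97098007 to 97115331), rose from 0.907 ± 1.66 to 30.0 ± 6.62 CPM (log2 fold change 4.97, SE 0.63, edgeR adjusted p = 1.29e-08).

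The other lineage genes moved less. The costimulatory receptor gene Icos (chromosome 1, 60960773 to 61000322) rose by 1.54 and the TH2 factor gene Gata3 (chromosome 2, 9857078 to 9887953) by 1.34. The cytokine gene Il21 (chromosome 3, 37222759 to 37232636) fell by 1.14 and Il2ra, the high-affinity IL-2 receptor chain (chromosome 2, 11642792 to 11693194), by 1.01. Pdcd1, the gene of the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), did not pass over all genes (33.6 ± 9.38 and 44.6 ± 9.32 CPM, edgeR adjusted p = 0.0727). It passed without Tfh2_4e4 replicate 1 (log2 fold change 0.47) or replicate 3 (0.52). The 6 largest rises by the naming rule were in S100a6 (a calcium-binding protein, 31.4 ± 22.0 to 480.4 ± 71.9 CPM), Nrn1 (neuritin), Tagap, Tg, Dock10 and Zbtb32. Their log2 fold changes ran from 2.86 to 3.93. Among the largest falls by that rule, Il10, the anti-inflammatory cytokine gene, was 1260 times lower (95% counting interval 225 to 49700) and Aqp3, a water and glycerol channel gene, 690 times lower (236 to 3350). Gpr15, a gut-homing receptor gene, was 227 times lower (62.6 to 1880), and Cysrt1 and Peli2 fell by 7.33 and 6.55.

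Of the TH17-associated list, 13 of 15 measured members fell and 1 rose (camera adjusted p = 3.66e-41). Among them were the chemokine gene Ccl20, at least 47.1-fold lower (a call that limma-voom did not make), the aryl hydrocarbon receptor gene Ahr (-4.98) and Tmem176a (-6.15). Where no second count is given here, the count adjusted over the list alone was the same. Of the TGF-beta and activin response list, whose genes are switched on by SMAD factors, 8 of 12 fell and 1 rose (camera adjusted p = 2.21e-09). Tgfbi was at least 46.4-fold lower, with Ldlrad4 at -4.95 and the feedback genes Skil at -2.67 and Smad7 at -1.51. The STAT3 response list had 8 of 14 members lower and 3 higher (camera adjusted p = 6.25e-09). The Treg-associated list had 6 of 13 lower and 4 higher (camera adjusted p = 0.00346), with the ectonucleotidase gene Nt5e at -5.46. Of the amino acid response list driven by ATF4, 20 of 21 rose and 0 fell (camera adjusted p = 2.32e-16). They included the asparagine synthetase gene Asns (2.60), Pck2 (2.26), Trib3 (2.24) and the folate enzyme gene Mthfd2 (2.17).

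Cell-cycle genes were higher in TfhA_4e4 and hypoxia and glycolysis genes lower. In the mitosis list 16 of 22 members rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 7.16e-07). Examples were the mitotic kinase gene Plk1 (0.99) and the cyclin gene Ccnb1 (0.96). The DNA replication list had 14 of 21 higher and 0 lower (camera adjusted p = 9.77e-06, and adjusted p = 0.0461 with an estimated correlation). The clamp loader gene Rfc3 stood at 1.55 and the thymidylate synthase gene Tyms at 1.42. Of the hypoxia response list 13 of 18 fell and 0 rose (camera adjusted p = 9.77e-06, and adjusted p = 0.0947 with an estimated correlation). The peptide hormone gene Adm stood at -2.13 and P4ha1 at -1.41. Glycolysis genes had 10 of 18 lower and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 0.00434, and adjusted p = 0.0979 with an estimated correlation). The glucose transporter gene Slc2a3 and the aldolase gene Aldoc were both at -1.21. The TH1-associated list had 10 of 17 higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.0947 with an estimated correlation). In it, the chemokine receptor gene Cxcr3 rose by 3.64 and Cxcr6 fell by 5.93. TFH-associated genes split into 8 of 26 higher and 8 lower (10 and 9 adjusted over the list alone, camera adjusted p = 0.115). The surface glycoprotein gene Cd200 stood at 2.84 and the transcriptional regulator gene Tox2 at -4.14. This list had a median log2 fold change of 0.03 and a mean of -0.09. By fry, which does not compare a list with other genes, it passed downward (adjusted p = 1.33e-07).

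In all, edgeR called 3729 of 11357 genes for TfhA_4e4 against Tfh2_4e4, 1757 higher (804 by more than 2-fold) and 1972 lower (795). Replicate 3 of Tfh2_4e4 held 4.22 CPM of Tbx21 against 0 to 0.967 in the other 5 libraries of its group. Without that library Tbx21 rose by 6.98 and Cxcr3 by 4.70, without TfhA_4e4 replicate 1 Cxcr5 fell by 4.39 and without replicate 3 Cysrt1 and Peli2 fell by 9.44 and 8.66. With the mitochondrial rRNA share, which was higher in every TfhA_4e4 library than the Tfh2_4e4 mean, as a covariate, 2722 genes were called and the rise of Gata3 was 0.76 and no longer passed.

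**Figure D1:**
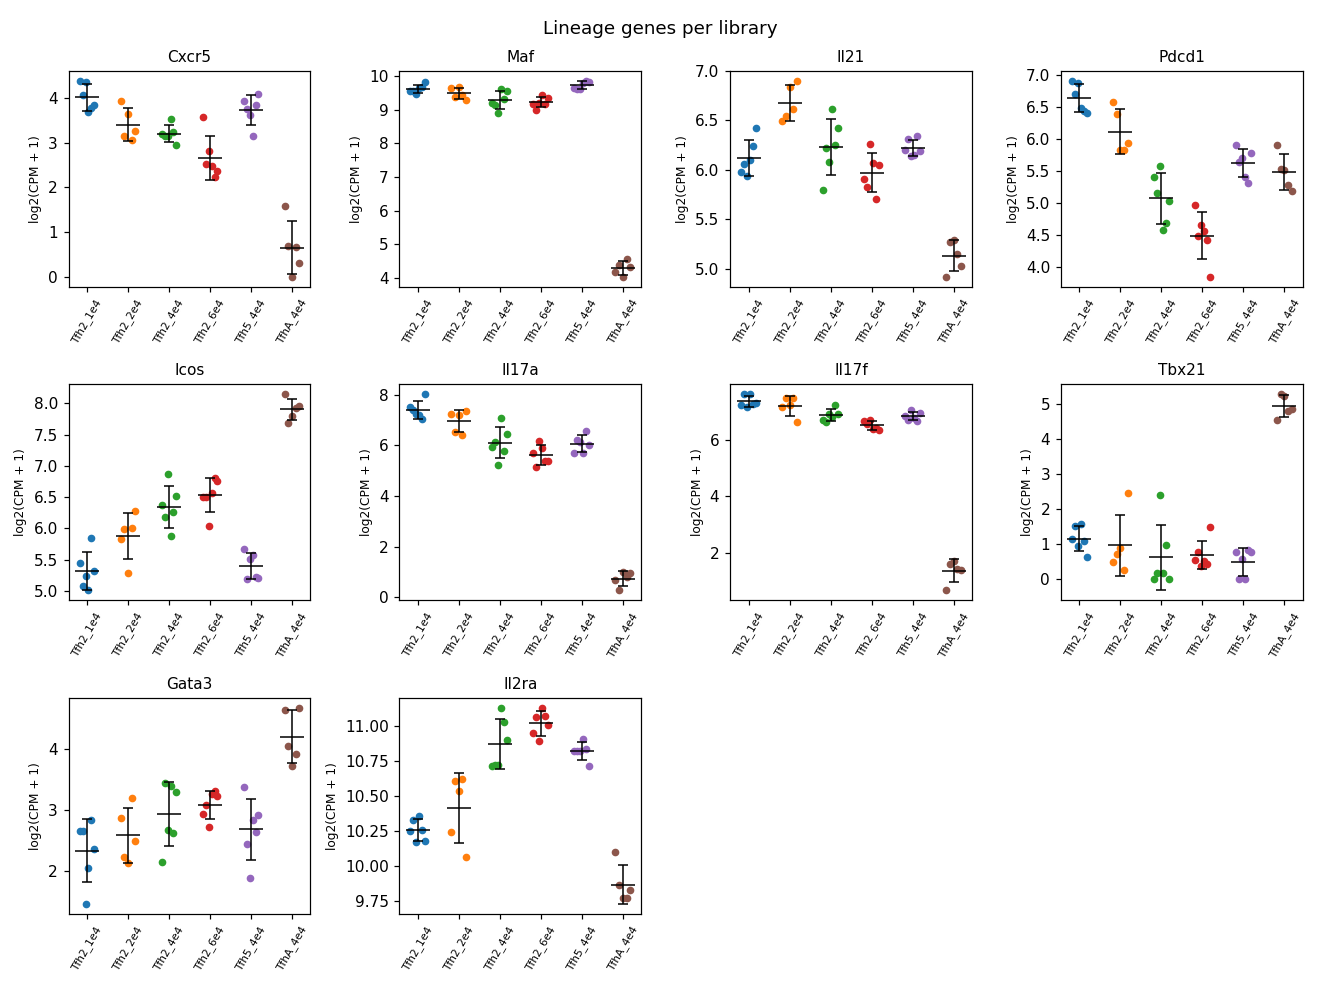
Normalized CPM of 10 of the 11 tested lineage genes on a log2(CPM + 1) axis, one point per library in the 6 groups, with the mean and SD of each group. Maf lay at 18.8 ± 2.72 CPM in TfhA_4e4 and at 629.6 ± 114.7 CPM in Tfh2_4e4, and Pdcd1 went from 99.9 CPM in Tfh2_1e4 to 22.0 CPM in Tfh2_6e4.

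Tfh5_4e4 differed from Tfh2_4e4 by a smaller set of genes. Of the lists tested, the SMAD response list had the lowest camera adjusted p, followed by the hypoxia response and glycolysis lists. Pmepa1, a SMAD-induced feedback gene, rose from 272 ± 24.1 to 485 ± 34.6 CPM (n = 6 each, log2 fold change 0.83, SE 0.086, edgeR adjusted p = 1.74e-08, higher in 6 of 6 libraries). Smad7, which blocks the receptor, rose by 0.88, Skil by 0.52 and the receptor gene Tgfbr1 itself by 1.09, while of the SMAD response list 6 of 12 members rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 3.73e-10). Icos went the other way, from 82.2 ± 19.7 to 41.6 ± 6.25 CPM (log2 fold change -0.98, edgeR adjusted p = 4.13e-05). The other named rises were Sox4 (an HMG-box transcription factor gene, 1.15), Pdlim5 (1.11), Rgs16 (1.11), Pcbp3 and Dnm3. The named falls were Podnl1 (-1.63), Selenbp1 (-1.47), the immune receptor gene Slamf7 (-1.46), Dpf1, Nrn1 (-1.49) and H2-Q7 (-1.20).

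Maf rose by 0.42 (SE 0.101, 845.1 ± 70.8 CPM in Tfh5_4e4, edgeR adjusted p = 0.00966). The TH17 genes Il17a (-0.13, adjusted p = 0.845) and Il17f (-0.04, 0.937) did not pass the edgeR test. Nor did Cxcr5 (0.60, 0.243), Il21 (-0.03, 0.944), Gata3 (-0.31, 0.685), Il2ra (-0.06, 0.84), Tbx21 (-1.17, 0.532) or Pdcd1 (0.54, 0.0661). Of the TH17-associated list 1 of 15 members fell, the receptor gene Il23r (-1.35), and 0 rose (0 and 2 lower adjusted over the list alone, camera adjusted p = 0.823). The TFH-associated list had 4 of 26 higher and 2 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.0395, and adjusted p = 0.0479 with an estimated correlation). In it Angptl2 stood at 0.76. Hypoxia response genes fell in 5 of 18 cases and rose in 0 (12 lower adjusted over the list alone, camera adjusted p = 1.96e-09, and adjusted p = 0.0479 with an estimated correlation). Adm stood at -1.34 and Ndrg1 at -0.68. Glycolysis genes fell in 6 of 18 and rose in 0 (11 lower adjusted over the list alone, camera adjusted p = 1.8e-08), with Slc2a3 at -0.88. In the mitosis list 2 of 22 fell and 0 rose (8 lower adjusted over the list alone, camera adjusted p = 7.58e-06, and adjusted p = 0.0306 with an estimated correlation). In the DNA replication list 4 of 21 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 1.63e-05, and adjusted p = 0.0862 with an estimated correlation).

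For this pair edgeR called 353 genes, 160 higher (28 by more than 2-fold) and 193 lower (44). It called 582 with the replicate block (269 higher, 313 lower), 519 with both ranges of replicate numbers as a factor and 274 without the Tfh2 libraries that carried genes high in TfhA_4e4 (Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6). Without Tfh2_4e4 replicate 3 the rise of Maf was 0.34 and no longer passed, and the fall of Nrn1 was -0.95 and no longer passed (nor did it, at -1.42, without Tfh5_4e4 replicate 2). There Pdcd1 passed at 0.64, and the value of Tbx21 turned to 0.83.

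TfhA_4e4 against Tfh5_4e4 gave the widest contrast of the 3 codes. Maf fell by 5.48 (SE 0.137, 845.1 ± 70.8 CPM, n = 6, to 18.8 ± 2.72 CPM, n = 5), Il17a by 6.55, Il17f by 6.07, Cxcr5 by 4.18, Il21 by 1.10 and Il2ra by 0.95. Tbx21 rose by 6.13, Icos by 2.53 and Gata3 by 1.65, and Pdcd1 did not pass (-0.13, edgeR adjusted p = 0.587). Nrn1 (4.74), S100a6 (4.09), Dock10 (3.77), Tg (3.74), the interferon-induced gene Trim30a (3.49) and the inhibitory receptor gene Btla (3.24) rose most under the naming rule. Il10 was 1260 times lower (95% counting interval 226 to 49900), Aqp3 1180 times (403 to 5720) and Gpr15 205 times (56.6 to 1700). Cysrt1 fell by 8.19 and Peli2 by 7.38 (10.3 and 9.48 without TfhA_4e4 replicate 3). The surface receptor gene Cd101 fell by 6.81, and Ccl20 and Tgfbi were at least 66.8-fold and 37.0-fold lower.

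Some of the lists moved as follows between these groups. STAT3 response genes fell in 8 of 14 cases and rose in 3 (camera adjusted p = 6.51e-06). Naive and quiescence genes fell in 12 of 17 and rose in 4 (13 and 4 adjusted over the list alone, camera adjusted p = 1.42e-05). p53 response genes rose in 8 of 11 and fell in 2 (camera adjusted p = 0.00762, and adjusted p = 0.0558 with an estimated correlation). Both mitochondrial rRNA genes, 2 of 3 nuclear RNAs and 5 of 8 mitochondrial mRNAs rose. TH17-associated genes fell in 13 of 15 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 1.65e-32). SMAD response genes fell in 10 of 12 and rose in 1 (camera adjusted p = 2.42e-13). ATF4 response genes rose in 20 of 21 cases and fell in 0 (camera adjusted p = 8.74e-15). Mitosis genes rose in 19 of 22 with 0 lower (camera adjusted p = 1.31e-09) and DNA replication genes in 16 of 21 with 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 4.09e-08). TH1-associated genes were higher in 12 of 17 and lower in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.0962 with an estimated correlation). TFH-associated genes were lower in 11 of 26 and higher in 8 (camera adjusted p = 0.0472, and adjusted p = 0.059 with an estimated correlation). Hypoxia response genes were lower in 8 of 18 and higher in 3 (camera adjusted p = 0.0915). Glycolysis genes were lower in 3 of 18 and higher in 1 (2 and 0 adjusted over the list alone, camera adjusted p = 0.607). edgeR called 4490 genes, 2174 higher (1071 by more than 2-fold) and 2316 lower (952). Without TfhA_4e4 replicate 1 Cxcr5 fell by 4.97, and with the fit limited to these groups the camera adjusted p of the TFH-associated list was 0.572.

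**Figure D2:**
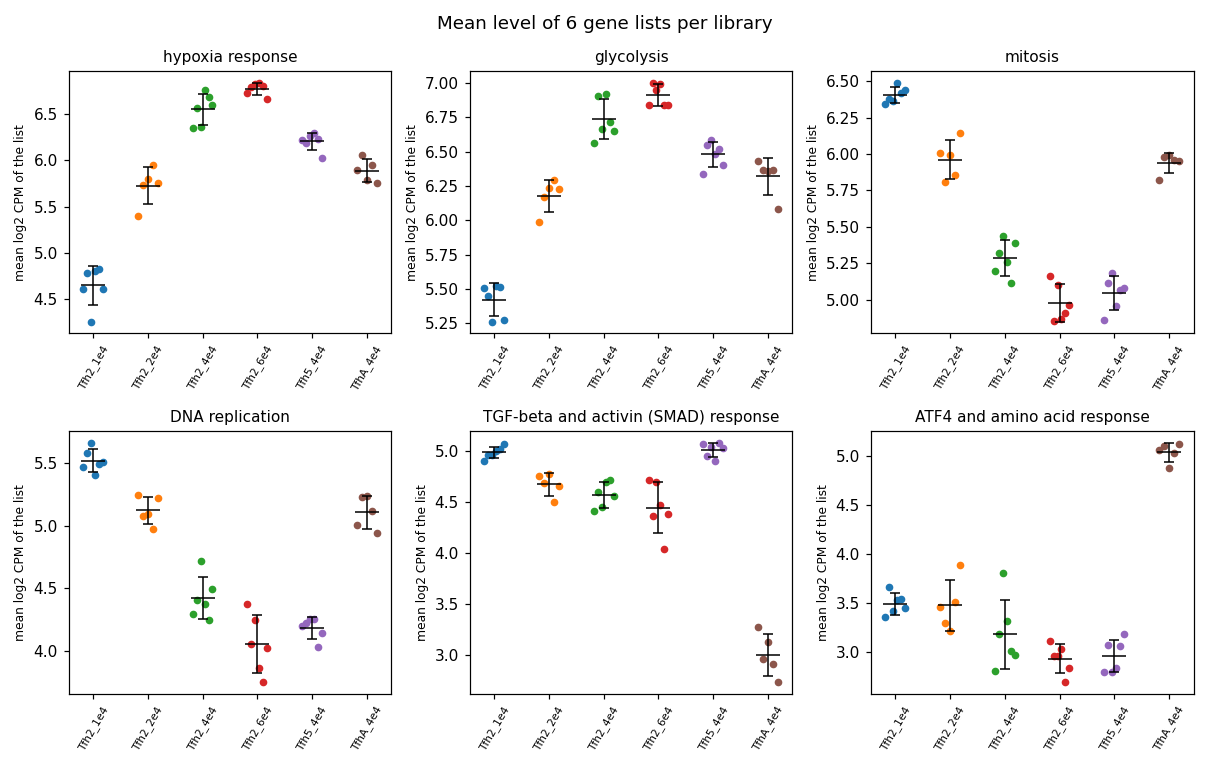
Mean log2 CPM of the members of 6 fixed gene lists (hypoxia response, glycolysis, mitosis, DNA replication, SMAD response, ATF4 response), one point per library in the 6 groups, with the mean and SD of each group. All 18 measured hypoxia response genes rose and all 22 mitosis genes fell per doubling of the label number within Tfh2.

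Within Tfh2, expression followed the number in the label. Slc2a3, the glucose transporter gene, went from 10.8 ± 1.69 CPM (n = 6) at 1e4 to 62.8 ± 19.5 (n = 5) at 2e4, 270.1 ± 55.6 (n = 6) at 4e4 and 416 ± 28.9 (n = 6) at 6e4. It rose by 2.08 on the log2 scale per doubling (SE 0.061, edgeR adjusted p = 3.45e-29). Selenbp1 rose by 3.29, the lysophospholipase gene Enpp2 by 2.52, Slamf7 by 2.37, Plcxd1 by 2.11 and the lipoprotein receptor gene Vldlr by 2.08 per doubling. Sox4 fell by 1.26 per doubling, from 236 ± 33.0 to 22.1 ± 5.84 CPM. It was followed by Marcksl1 (-1.20), Tyms (-1.07), Angptl2 (-1.07), the ribonucleotide reductase gene Rrm2 (-1.05) and Marcks (-1.05).

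Lineage genes moved by smaller steps. Pdcd1 fell by 0.86 per doubling (SE 0.06, edgeR adjusted p = 3.52e-16), with group means of 99.9, 70.1, 33.6 and 22.0 CPM from 1e4 to 6e4. Il17a fell by 0.70 (173, 128, 73.7 and 49.6 CPM), Cxcr5 by 0.51 (15.5, 9.86, 8.26 and 5.70 CPM), Il17f by 0.33 and Maf by 0.15, from 781 ± 69.1 to 596 ± 63.5 CPM. Icos rose by 0.48, Gata3 by 0.33 and Il2ra by 0.31 per doubling. Il21 (-0.09, edgeR adjusted p = 0.083) and Tbx21 (-0.35, 0.245) did not pass.

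Of the hypoxia response list, genes induced when oxygen is short, all 18 measured members rose with the number (camera adjusted p = 1.36e-34). Examples were Adm (2.76), Ndrg1 (1.71) and the growth factor gene Vegfa (1.09 per doubling). Glycolysis genes rose in 16 of 18 cases and fell in 0 (camera adjusted p = 2.81e-20), with Aldoc at 1.40 and the hexokinase gene Hk2 at 0.65. All 22 mitosis genes fell (camera adjusted p = 1.74e-23), with the survivin gene Birc5 at -0.72 and Plk1 at -0.63. Of the DNA replication list 20 of 21 members fell with 0 higher (21 lower adjusted over the list alone, camera adjusted p = 2.41e-18), with Cdc6 at -0.84. Cholesterol synthesis genes fell in 19 of 22 cases with 0 higher (camera adjusted p = 1.45e-06), for example Cyp51 (-0.55). Unfolded protein response genes fell in 11 of 14 with 0 higher (camera adjusted p = 0.000104), for example the chaperone gene Hspa5 (-0.39). STAT3 response genes rose in 11 of 14 cases and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 1.54e-07). SMAD response genes fell in 6 of 12 and rose in 1 (camera adjusted p = 0.00561), with Pmepa1 at -0.66. TFH-associated genes rose in 7 of 26 cases and fell in 9 (8 and 9 adjusted over the list alone, camera adjusted p = 0.113, and adjusted p from 0.0315 with the replicate block to 0.12 over the camera alternatives). TH17-associated genes rose in 5 of 15 and fell in 6 (camera adjusted p = 0.357). By fry, which does not compare a list with other genes, the TFH-associated (adjusted p = 1.14e-07) and TH17-associated (0.00077) lists passed downward.

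Per doubling of the number edgeR called 5331 genes, 2737 rising (275 by more than 2-fold) and 2594 falling (99). Tbx21 passed at -0.67 without Tfh2_4e4 replicate 3. Il21 passed without Tfh2_1e4 replicate 1 (-0.11), 2 (-0.10) or 3 (-0.11), Tfh2_4e4 replicate 4 (-0.11) or Tfh2_6e4 replicate 3 (-0.12). With the share of counts in identifiers 100861531 and 19791 as a covariate the rise of Gata3 was 0.27 and no longer passed.

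Between the ends of the range, Tfh2_6e4 against Tfh2_1e4, Slc2a3 rose by 5.27 (SE 0.164, n = 6 each, edgeR adjusted p = 5.07e-28, higher in 6 of 6 libraries). Selenbp1 rose by 8.51, Enpp2 by 6.45, Slamf7 by 6.18, Plcxd1 by 5.46 and Vldlr by 5.36. Sox4 fell by 3.41, Marcksl1 by 3.14, Tyms by 2.76, Rrm2 by 2.75, Pdlim5 by 2.73 and Angptl2 by 2.69. Pdcd1 fell by 2.18, Il17a by 1.80, Cxcr5 by 1.43, Il17f by 0.87 and Maf by 0.39. Icos rose by 1.22, Il2ra by 0.76 and Gata3 by 0.81. Il21 (-0.15, edgeR adjusted p = 0.287) and Tbx21 (-0.87, 0.323) did not pass. All 18 hypoxia response genes rose (camera adjusted p = 2.67e-35), and 16 of 18 glycolysis genes rose and 0 fell (2.35e-20). All 22 mitosis genes fell (camera adjusted p = 1.97e-22) and 19 of 21 DNA replication genes fell with 0 higher (21 adjusted over the list alone, camera adjusted p = 9.82e-18). edgeR called 4888 genes, 2537 higher (1145 by more than 2-fold) and 2351 lower (843). Without Tfh2_1e4 replicate 3 the rise of Gata3 was 0.63 and no longer passed, and Tbx21 stood at -1.47 without Tfh2_6e4 replicate 6.

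From 1e4 to 2e4 Slc2a3 rose by 2.54 (SE 0.156, 10.8 ± 1.69 CPM, n = 6, to 62.8 ± 19.5 CPM, n = 5, edgeR adjusted p = 4.36e-16), Ndrg1 by 2.54 and Aldoc by 2.25. Of the 18 hypoxia response genes 17 rose and 0 fell (18 adjusted over the list alone, camera adjusted p = 2.31e-53). Glycolysis genes rose in 11 of 18 cases with 0 lower (13 adjusted over the list alone, camera adjusted p = 9.04e-29). Mitosis genes fell in 11 of 22 with 0 higher (18 adjusted over the list alone, camera adjusted p = 5.74e-15) and DNA replication genes in 4 of 21 with 0 higher (10 adjusted over the list alone, camera adjusted p = 1.83e-08). Other rises by the naming rule were those of Selenbp1 (5.10), Plcxd1 (3.46), Slamf7 (3.45), Vldlr (3.20), the MHC class II gene H2-Ab1 (3.05) and Enpp2 (2.72). Falls by that rule were those of Rrm2 (-1.04), Maged1, the protease inhibitor gene Timp2, Sox4 (-0.93), Marcksl1 (-0.93) and Tgfbr1 (-0.93). The call of Maged1 ended without any one of Tfh2_1e4 replicates 2 (-0.94) and 4 (-0.95) and Tfh2_2e4 replicates 1 (-0.92), 5 (-0.89) and 6 (-0.95). Il21 rose by 0.56 (69.2 ± 9.28 to 102 ± 13.1 CPM, edgeR adjusted p = 0.00115) and Icos by 0.58 (0.018). Pdcd1 (-0.51, 0.0725), Cxcr5 (-0.65, 0.182), Il17a (-0.44, 0.307), Il17f (-0.16, 0.651), Maf (-0.12, 0.671), Gata3 (0.27, 0.772), Il2ra (0.17, 0.374) and Tbx21 (0.19, 0.946) did not pass. edgeR called 597 genes, 461 higher and 136 lower. The call of Icos ended without Tfh2_1e4 replicate 2 (0.52) or 4 (0.51) or Tfh2_2e4 replicate 6 (0.45). Pdcd1 passed at -0.65 without Tfh2_2e4 replicate 1, and Tbx21 turned to -1.22 without Tfh2_2e4 replicate 6.

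From 2e4 to 4e4 mitosis genes fell in 18 of 22 cases with 0 higher (21 adjusted over the list alone, camera adjusted p = 9.95e-19). DNA replication genes fell in 15 of 21 with 0 higher (17 adjusted over the list alone, camera adjusted p = 5.66e-15), among them the flap endonuclease gene Fen1 (-1.33). Hypoxia response genes rose in 13 of 18 with 0 lower (14 adjusted over the list alone, camera adjusted p = 5.77e-22). Glycolysis genes rose in 12 of 18 with 0 lower (camera adjusted p = 3.52e-14), and Slc2a3 by 2.11 (SE 0.15). Cholesterol synthesis genes fell in 10 of 22 with 0 higher (11 adjusted over the list alone, camera adjusted p = 1.25e-07). TFH-associated genes fell in 8 of 26 with 4 higher (9 and 4 adjusted over the list alone, camera adjusted p = 0.00205). Other large rises were those of Selenbp1 (2.69), Enpp2 (2.59), the cytokine gene Il24 (2.52), Dpf1 (2.48), the integrin gene Itga7 (2.35) and Matk (2.17). Other large falls were those of Rgs16 (-1.61), Marcks (-1.34), the immediate early gene Egr1 (-1.33), Angptl2 (-1.32) and Fam111a (-1.27). Pdcd1 fell by 1.06 (SE 0.173, edgeR adjusted p = 1.46e-05), Il17a by 0.80 (0.00827) and Il21 by 0.44 (0.00829). Il2ra rose by 0.45 (edgeR adjusted p = 0.000521) and Icos by 0.47 (0.0408). Il17f (-0.35, 0.0634), Cxcr5 (-0.26, 0.624), Maf (-0.19, 0.275), Gata3 (0.45, 0.373) and Tbx21 (-0.61, 0.649) did not pass. edgeR called 1475 genes, 862 higher and 613 lower. It called 1201 without Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6, where Il17a (-0.58) and Il21 (-0.37) no longer passed. Leaving out any one of Tfh2_2e4 replicates 1 (0.44), 4 (0.34) and 5 (0.48) and Tfh2_4e4 replicates 1 (0.46), 3 (0.34) and 6 (0.44) ended the call of Icos. Il17f passed without Tfh2_2e4 replicate 6 (-0.49) or Tfh2_4e4 replicate 5 (-0.44), and Tbx21 passed at -2.63 without Tfh2_4e4 replicate 3 and turned to 0.76 without Tfh2_2e4 replicate 6.

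From 4e4 to 6e4 fewer genes moved and none of the lineage genes named here passed over all genes (3 were lower and 0 higher adjusted over the list alone). The earlier steps each doubled the number, but this step is less than a doubling. Its counts and changes therefore cannot be set against theirs at an equal step, and they do not show that expression levelled off above 4e4. Sox4 fell from 58.2 ± 18.6 to 22.1 ± 5.84 CPM (n = 6 each, log2 fold change -1.39, SE 0.178, edgeR adjusted p = 4.07e-06), the condensin gene Ncapg2 by 1.18, Itpripl2 by 1.17, the thymidine kinase gene Tk1 by 1.06, the chemokine receptor gene Ccr6 by 0.83 and Pmepa1 by 0.49. Ly6c1 rose by 1.12 (126 ± 28.1 to 275 ± 46.4 CPM), Lrrc32, which holds latent TGF-beta at the cell surface, by 1.04, Neb by 0.91 and Slc2a3 by 0.62. DNA replication genes fell in 4 of 21 cases with 0 higher (11 adjusted over the list alone, camera adjusted p = 3.17e-10), with the helicase gene Mcm5 at -0.77. Mitosis genes fell in 1 of 22 with 0 higher (4 adjusted over the list alone, camera adjusted p = 7.32e-08). Of the hypoxia response list 0 of 18 passed (4 higher adjusted over the list alone, camera adjusted p = 3.48e-05, and adjusted p = 0.134 with an estimated correlation). Pdcd1 (-0.61, edgeR adjusted p = 0.0577), Il17a (-0.57, 0.183), Il17f (-0.37, 0.13), Cxcr5 (-0.52, 0.425), Maf (-0.08, 0.831), Il21 (-0.28, 0.272), Icos (0.17, 0.717), Gata3 (0.09, 0.945), Il2ra (0.14, 0.547) and Tbx21 (-0.45, 0.885) stayed below the threshold. edgeR called 168 genes, 70 higher (8 by more than 2-fold) and 98 lower (24). By limma-voom 121 were higher and 60 lower, and in a fit of only these groups 45 and 29, so the balance of directions depended on the method. DESeq2 called 275 (138 higher, 137 lower). edgeR called 381 with the replicate block, 303 with both ranges of replicate numbers as a factor and 90 without Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6. The count became 81 without Tfh2_4e4 replicate 1, 75 without replicate 3 and 269 without replicate 4, and 96, 108 and 55 without Tfh2_6e4 replicates 2, 4 and 5. Pdcd1 passed without Tfh2_4e4 replicate 4 (-0.69) or 5 (-0.68) or Tfh2_6e4 replicate 1 (-0.73), and Tbx21 turned to 1.57 without Tfh2_4e4 replicate 3.

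Genes lower in TfhA_4e4 and higher in Tfh5_4e4 than in Tfh2_4e4 numbered 114, where independent lists would share 27.8, and genes higher in TfhA_4e4 and lower in Tfh5_4e4 numbered 75 against 29.9. Both groups shared 60 lower genes against 33.5 and 8 higher genes against 24.8. Across the 11357 genes, which are not independent replicates, the log2 fold changes correlated at r = -0.207 (jackknife SE over 17 libraries 0.193, Spearman -0.106). In 20 draws of groups from one mean with the same shared control r was at least 0.428. The covariance of the draws was 0.0474 to 0.0569, where the observed covariance was -0.114. Each gene was drawn independently, so the range of the draws leaves out shifts that genes share and may understate the spread by chance. The draws therefore cannot show that the code effects oppose each other. With the control split between the effects r was -0.107 and -0.377, and genes lower in both numbered 34 against 15.6 and 21 against 23.6. Without Tfh2_4e4 replicate 3 r was 0.00326 and the covariance 0.00188, still below those draws. The overlaps were then 65 against 17.8 and 49 against 25.5 in the opposite directions, 67 against 29.3 lower in both and 9 against 15.5 higher in both.

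Across genes the Tfh5_4e4 effect tended to run against the number effect, but not in the cell-cycle lists. The median log2 fold change of the mitosis list was -0.30 in Tfh5_4e4 against Tfh2_4e4 and -1.38 in Tfh2_6e4 against Tfh2_1e4. That of the DNA replication list was -0.34 and -1.22. Genes higher in Tfh5_4e4 and lower in Tfh2_6e4 than in Tfh2_1e4 numbered 118 against 33.1 for independent lists, as did 148 against 43.1 in the opposite sense, with r = -0.263 across genes (jackknife SE 0.0901, Spearman -0.231). For TfhA_4e4 the overlaps were 814 genes lower in TfhA_4e4 and higher at 6e4 against 441, and 599 higher in TfhA_4e4 and lower at 6e4 against 364. Its correlation across genes was -0.0389 (jackknife SE 0.0316) by Pearson and -0.13 by Spearman.

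**Figure D3:**
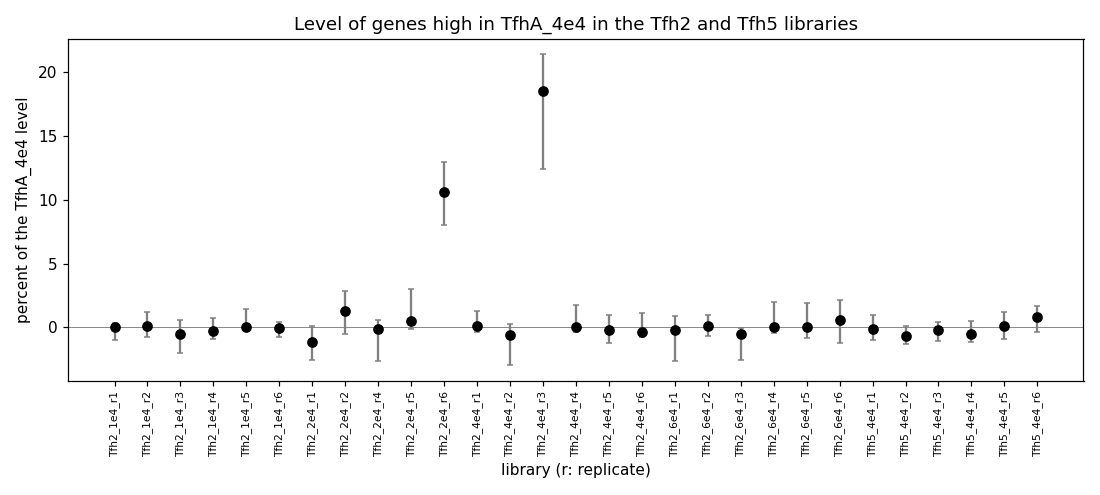
Expression of 21 genes high in TfhA_4e4 as a percentage of the TfhA_4e4 level in each Tfh2 and Tfh5 library, with the median and the 25th to 75th percentile over the genes. Replicate 3 of Tfh2_4e4 stood at a median of 18.5% and replicate 6 of Tfh2_2e4 at 10.6%, and the other libraries between -1.16% and 1.26%.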

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

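The tests of RNA from other cell types and of an exchanged sample label, the fit with all libraries thinned to one depth and the fit with the mitochondrial rRNA share as a covariate were chosen after the results were seen. In 258 groups of values per library, 16 had 1 library farther from the rest than Dixon's critical value, and chance gives about 1 in 20, or 12.9.

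Libraries stood apart in the following lineage genes and lists, each given as mean log2 CPM with the gap as a share of the range. In Tfh2_4e4 replicate 3 the TFH-associated list was at 4.323 against 3.963 in the other libraries (0.851) and the TH1-associated list at 2.327 against 0.9913 (0.773). The TH17-associated list in Tfh2_1e4 replicate 6 was at 5.364 against 5.074 (0.733). In TfhA_4e4 replicate 1, Il17f was at -0.4572 against 1.03 (0.735), Il2ra at 10.1 against 9.805 (0.719) and the mitosis list at 5.823 against 5.969 (0.752). TfhA_4e4 replicate 6 had the glycolysis list at 6.085 against 6.381 (0.802). Tfh5_4e4 replicate 4 had the T cell cytokine list at 1.445 against 2.023 (0.679) and the unfolded protein response list at 5.29 against 5.369 (0.751). The IL-2 and STAT5 response list was at 4.925 against 5.307 in Tfh2_6e4 replicate 1 (0.684), and the retinoic acid response list at 2.934 against 3.322 in Tfh2_2e4 replicate 2 (0.812). The mitochondrial rRNA share of Tfh2_4e4 replicate 2 was 8.06% against 10.29% (0.645). More genes had a count in Tfh2_1e4 replicate 6 (13140 against 12520, 0.701), Tfh2_2e4 replicate 6 (13240 against 12390, 0.801), Tfh2_6e4 replicate 3 (12650 against 12370, 0.679) and TfhA_4e4 replicate 5 (13280 against 12810, 0.823) than in the rest of their groups.

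Genes high in TfhA_4e4 were raised in Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6, where 20 of 21 such genes, chosen against Tfh5_4e4 without any Tfh2 library, lay above the other libraries of the group. Over the 21 genes the share of the TfhA_4e4 level had a median of 18.5% (25th to 75th percentile 12.4% to 21.4%) and 10.6% (8.06% to 13%). The percentile ratio was at most 1.73, which is consistent with RNA, reads or cells of the TfhA_4e4 kind mixed in. An exchanged label is argued against by Maf, which stood at 72.3% and 84.9% of the other libraries of the group where TfhA_4e4 stood at 2.99%. B cell, myeloid, dendritic or CD8 T cells are argued against by 27 of their markers, those under 1 CPM in the other libraries of the group, a limit set after the values were seen, which summed to 3.75 and 4.17 CPM (1.45 to 5.55 and 1.1 to 3.6 in the other libraries of each group), although the gate of the sort is not given. H2-Aa, Lyz2 and Cd8a had 0 counts, Cd74 at most 1 and Cd79a 0 and 2. H2-Ab1, which the limit left out, stood at 69.7 and 33.8 CPM against 74.8 ± 10.3 (n = 5) and 27.3 ± 10.8 (n = 4) in the others, and Cd8b1 at 5.86 and 7.14 CPM against 7.95 ± 2.27 and 5.93 ± 2.13. The cytotoxic gene Nkg7, which is 1 of the 21 genes, was higher, at 19 and 11.3 CPM against 0.885 ± 0.865 and 3.38 ± 2.18, with 107 CPM in TfhA_4e4. Cells within these cultures that had taken the same state would give the same values, so this stays open beside a mixture.

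In TfhA_4e4 the depth was lower and the mitochondrial rRNA share higher than in Tfh2_4e4, along with the 3729 called genes. Lower depth could not account for the calls, since 3523 genes were called with all libraries thinned to one depth. An RNA quality effect carried by the mitochondrial share is unlikely as the whole cause, since 58.5% of the called genes kept their sign and passed with that share as a covariate, Maf and Tbx21 among them. Of the variance of that share 73.1% lay between groups, so the covariate also takes up part of any true difference, and the genes whose calls ended, such as Gata3 and Tnfrsf9, stay open. The codes themselves, which the labels leave undefined, stay open as a biological difference.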

How the results depend on the processing

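The fits without the Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6 libraries, without the large identifiers, on replicate numbers 1 to 3 or 4 to 6 alone, thinned, or with a covariate were chosen after the data were seen, as was leaving out libraries for the correlations. Over the values of named genes, RLE size factors left 775 on the same side of the threshold and weakened 3, no filter left 764 and weakened 9, DESeq2 left 770 and weakened 5, limma-voom left 760 and weakened 15, the replicate block left 769 and weakened 3, a fit of only the groups compared left 741 and weakened 30, and leaving out 1 library left 9864 and weakened 404. Values brought over the threshold numbered 5 with no filter, 3 with DESeq2, 3 with limma-voom and 6 with the replicate block. They numbered 1 with only the groups compared and 16 with 1 library left out. A stricter filter left 774, weakened 2 and brought over 2. Both ranges of numbers as a factor left 772, weakened 1 and brought over 5. Without the 2 libraries 731 stayed and 43 weakened, on numbers 1 to 3 alone 596 and 180, and on numbers 4 to 6 alone 661 and 114. With the mitochondrial covariate, in TfhA_4e4 against Tfh2_4e4, 95 stayed, 20 weakened and 4 reversed. With an estimated correlation 29 list calls were lost. These were 7 of 17 for TfhA_4e4 against Tfh2_4e4, 1 of 6 for Tfh5_4e4 against Tfh2_4e4 and 6 of 14 for TfhA_4e4 against Tfh5_4e4. A further 3 of 17 were lost for the slope and for 6e4 against 1e4 each. For the steps from 1e4 to 6e4 the losses were 2 of 15, 2 of 16 and 5 of 11. With fry, which does not compare a list with other genes, 40 list calls were gained and 1 was lost. Counts of called genes moved by over 1.5 times as follows, with fewer libraries where a range of numbers was taken alone and the cause otherwise not tested. TfhA_4e4 against Tfh2_4e4 gave 2300 genes on numbers 1 to 3, and TfhA_4e4 against Tfh5_4e4 2832 on numbers 4 to 6. Tfh5_4e4 against Tfh2_4e4 gave 582 with the block, 96 on numbers 1 to 3 and 122 on numbers 4 to 6. Tfh2_6e4 against Tfh2_1e4 gave 3243 on numbers 1 to 3, Tfh2_2e4 against Tfh2_1e4 141 and 359 on numbers 1 to 3 and 4 to 6, and Tfh2_4e4 against Tfh2_2e4 457 on numbers 1 to 3. Tfh2_6e4 against Tfh2_4e4 gave 275 with DESeq2, 74 with only its groups, 381 with the block, 303 with both ranges of numbers as a factor, 90 without Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6, and 23 and 34 on numbers 1 to 3 and 4 to 6. With 1 library left out the counts ran from 3392 to 3767 (TfhA_4e4 against Tfh2_4e4), 239 to 405 (Tfh5_4e4 against Tfh2_4e4), 4180 to 4389 (TfhA_4e4 against Tfh5_4e4), 5111 to 5419 (slope), 4619 to 4825 (6e4 against 1e4), 437 to 602 (2e4 against 1e4), 1140 to 1502 (4e4 against 2e4) and 55 to 269 (6e4 against 4e4). The correlation of the code effects ran from -0.22 to 0.00326 with 1 library left out, that of TfhA_4e4 with the number effect from -0.0546 to -0.024 (-0.13 by Spearman, -0.127 over genes of mean log2 CPM at least 3), and that of Tfh5_4e4 from -0.321 to -0.217 (-0.364 over those genes). With the mitochondrial rRNA share as a covariate mt-Rnr2 turned to -0.25, ND2 to -0.27, ND4 to -0.24 and ND5 to -0.43. The covariate holds the counts of mt-Rnr2 itself, and for the 3 mRNAs the cause was not tested. Depth limits lineage genes near the floor such as Ifng and Il4.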

Other observations

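The tests of less oxygen and of more cell division, and the fit with the share of identifiers 100861531 and 19791 as a covariate, were chosen after the results were seen.

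Further gene groups moved between the codes. In TfhA_4e4 against Tfh2_4e4 the p53 response list had 8 of 11 members higher and 2 lower (camera adjusted p = 0.00057), with Phlda3 at 2.80, and the naive and quiescence list 9 of 17 lower and 4 higher (11 and 4 adjusted over the list alone, camera adjusted p = 2.07e-05), with the factor gene Foxo1 at -1.93 and the IL-7 receptor gene Il7r at -1.87. Cholesterol synthesis genes rose in 8 of 22 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0245, and adjusted p = 0.0947 with an estimated correlation). Type I interferon genes rose in 6 of 14 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0218, and adjusted p = 0.0782 with an estimated correlation). Chemokine receptor genes fell in 7 of 18 and rose in 4 (8 and 5 adjusted over the list alone, camera adjusted p = 0.0499, and adjusted p = 0.123 with an estimated correlation). Of the AHR response list 3 of 4 fell (4 adjusted over the list alone, too few for a list test). T cell cytokine genes rose in 8 of 21 and fell in 9 (9 and 9 adjusted over the list alone, camera adjusted p = 0.0961), with a median of 0.37 and a mean of -0.39. The IL-2 and STAT5 response list had 7 of 14 higher and 4 lower (camera adjusted p = 0.0822, and 0.0209 without Tfh2_4e4 replicate 3 and Tfh2_2e4 replicate 6), with the survival gene Bcl2 at 2.20. The lists of TCR-induced early genes (8 of 17 higher, 3 lower, camera adjusted p = 0.0961), retinoic acid response (3 of 8 higher, 3 lower, 0.815, median 0.24 and mean -0.18), oxidative phosphorylation (8 of 27 higher, 2 lower, 9 and 3 adjusted over the list alone, 0.0822), unfolded protein response (2 of 14 higher, 2 lower, 0.75), co-inhibitory receptors (2 of 8 higher, 2 lower, 4 and 2 adjusted over the list alone, 0.612), TH2-associated genes (2 of 6 higher, 2 lower, 3 and 2 adjusted over the list alone, 0.617), ribosomal proteins (4 of 77 higher, 4 lower, 2 and 4 adjusted over the list alone, 0.943) and heat shock (2 of 8 higher, 2 lower, 0.667, median 0.08 and mean -0.16) did not pass. Those results are by camera. By fry the TCR-induced early genes (adjusted p = 6.67e-05), oxidative phosphorylation (0.0209) and IL-2 and STAT5 response (5.23e-05) lists passed upward. The TFH-associated (fry adjusted p = 1.33e-07), T cell cytokine (4.6e-06) and unfolded protein response (0.0472) lists passed downward. The mitochondrial rRNA genes both rose, with mt-Rnr2 at 0.60. So did 6 of 8 mitochondrial mRNAs (camera adjusted p = 0.0151, and adjusted p = 0.352 with an estimated correlation) and 2 of 3 nuclear RNAs, with Malat1 at 1.08.

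With the label number, within Tfh2, naive and quiescence genes rose in 10 of 17 cases and fell in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000853). Retinoic acid response genes rose in 6 of 8 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000976), with the transglutaminase gene Tgm2 at 1.24, Treg-associated genes rose in 7 of 13 and fell in 3 (camera adjusted p = 0.00547), with Lrrc32 at 1.72, and TH2-associated genes rose in 4 of 6 and fell in 1 (camera adjusted p = 0.0061). T cell cytokine genes fell in 10 of 21 and rose in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00561). Ribosomal protein genes rose in 40 of 77 and fell in 3 (camera adjusted p = 0.00134, and adjusted p = 0.135 with an estimated correlation), and oxidative phosphorylation genes fell in 18 of 27 and rose in 0 (camera adjusted p = 0.00268, and adjusted p = 0.269 with an estimated correlation). Markers of other cells were scarce: 0 of 11 myeloid and 0 of 9 erythroid and platelet genes passed the filter on low counts, with 1 of 9 B cell, 4 of 9 dendritic and MHC class II, 2 of 8 CD8 T and NK, 1 of 6 gamma-delta T and 1 of 5 mast cell genes. Of these, 2 dendritic and MHC class II genes were higher and 2 lower in TfhA_4e4 than in Tfh2_4e4, and 1 CD8 T and NK gene (Klrd1) lower. In Tfh5_4e4 against Tfh2_4e4 the B cell gene Ighm was higher (0.89, 0.0235) and H2-Ab1 lower (-0.92, 0.00383). Per doubling of the number the B cell gene fell, 1 dendritic and MHC class II gene rose and 1 fell, and 1 CD8 T and NK gene rose. The sex-linked list had 0 of 4 members called in TfhA_4e4 against Tfh2_4e4.

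Genes moved with the label number of Tfh2 in hypoxia and division lists together. The share of counts in identifiers 100861531 and 19791 is unlikely as the whole cause, since 78% of the called genes kept their sign and passed with that share as a covariate. Less oxygen at a higher number and more cell division at a lower number cannot be told apart from other causes. Their tests were the rise of the hypoxia response list (camera adjusted p = 4.21e-05 with an estimated correlation) and the fall of the mitosis and DNA replication lists (at most 0.000223), the same movements that raised the question. No measurement of oxygen or division was among these data, and the labels do not give the unit of the number.

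Other splits of the libraries into groups of the same sizes, 100 for each comparison with the real one included, were fitted for each count of called genes. Such splits cannot exclude a chance difference between cultures, since the labels do not say that replicates were separate cultures. For TfhA_4e4 against Tfh2_4e4 only the real split (1 of 100) gave as many as 3729 genes, and the highest other gave 1000. The same held for Tfh5_4e4 against Tfh2_4e4 (353 genes, highest other 45), TfhA_4e4 against Tfh5_4e4 (4490 and 3309), the slope (5331 and 2337), Tfh2_6e4 against Tfh2_1e4 (4888 and 2497), Tfh2_2e4 against Tfh2_1e4 (597 and 334) and Tfh2_4e4 against Tfh2_2e4 (1475 and 851). For Tfh2_6e4 against Tfh2_4e4, 2 of 100 splits gave at least the 168 genes of the real split, a share under the threshold of 0.05. The highest other gave 335, so the real split was not the most extreme and chance is not excluded. The split of numbers 1 to 3 from 4 to 6, counted apart, gave 76 genes for this pair, 47 for Tfh5_4e4 against Tfh2_4e4 and at most 1 for each other pair (for 2e4 against 1e4 the sizes let it follow the numbers only nearly).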
